A study of Gallus gallus with 2 samples.

How the data were processed

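Thymus from female chickens of 5 weeks was flash frozen, its nuclei were isolated with an automated instrument, and libraries were made with 10x Genomics 3′ droplet chemistry, per the labels' protocols. Those protocols name more than one kit version and more than one sequencer, and neither was used here. The authors deposited whole-number UMI counts per gene and barcode, 1 matrix for each of the 2 libraries, with no normalization. The counts were made with Cell Ranger 7.0.1 on the GRCg7b assembly, per the submitters' processing notes, with the annotation restricted to protein-coding and long non-coding RNA genes, per the labels' protocols, whose text breaks off at that point. The names of the deposited matrices refer to CellBender, a correction that subtracts the RNA free in the droplets. Its version and settings are not given in the sources used here. Such a correction removes UMIs nucleus by nucleus, so a count of 0 can reflect that removal as well as a low level. A deposited cell annotation was not used here, so class names were rebuilt from marker genes and can differ from the study's own.

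The matrices listed 28951 genes, 12907 with a symbol and 16044 with an Ensembl identifier only. Genes without a symbol took part in clustering and tests but are not named, apart from the gene with most UMIs. Gene positions came from the RefSeq table of the same assembly, matched by symbol. Replicate 1 held 6564 barcodes and replicate 2 6050, and 10 barcode sequences occurred in both. Nuclei needed at least 200 detected genes and at most 5% mitochondrial UMIs, which left out 1393 and 476 barcodes for few genes and 1 barcode, of replicate 2, for mitochondrial UMIs. Mitochondrial transcripts made up only 0.00874% and 0.00600% of UMIs. Doublets were scored in each library by the share of simulated doublets (2 per nucleus) among each nucleus's neighbours. The score showed no valley between single nuclei and doublets, so the 6% with the highest scores were removed, 310 and 334 nuclei. This rate was set after the scores were seen. The analysed nuclei held 3840630 and 5350970 UMIs.

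For clustering, counts were scaled to 10000 per nucleus and transformed as log1p, and the 2000 most variable genes were chosen by their rank of dispersion within each library. Genes of the held-out lists below were kept out of these features. Some genes that were tested are not reported here. Values were scaled within each library and limited to 10, and 30 principal components, 15 nearest neighbours, shared-neighbour weights and Leiden clustering at resolution 1 gave 19 clusters, of which 13 were T lineage. Clusters were named only from 26 lists of marker genes of thymocyte stages and of other cell types that the organ can hold. A name required at least 3 detected markers (10 or more UMIs), and clusters with markers of more than one class stayed unnamed. Of the marker lists, those of the classes and stages in the report gave a name and the others gave none. The scoring rule of the stages was adjusted after a cluster with DP genes had first stayed unnamed. T-lineage clusters that no list named keep a number. Of the held-out genes, HMGB1 was among the leading genes of the early DN-like cluster although it was not a clustering feature. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.

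UMI counts were summed per library and class, or per library and stage, for groups with at least 20 nuclei in each library, since nuclei are not replicates. The sums were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, estimateDisp, glmQLFit and glmQLFTest, two-sided) with the library as a block, because the classes and stages of 1 library share that library. Classes were fitted together, as were stages, sharing 1 estimate of the spread, with 4 and 5 residual degrees of freedom. Each class was contrasted with the unweighted mean of the other tested classes on the log scale, and each stage with DP-like nuclei. Without the features that define clusters, 2628 genes were tested for classes and 6028 for stages. Genes varying with these in the same nuclei remain, so p-values are not independent of clustering. Adjusted p-values follow Benjamini and Hochberg, threshold 0.05. SEs of log2 fold changes come from the F statistic. The level given for the other classes is the mean of their CPM. A fitted fold change of a gene at 0 UMIs on 1 side depends on the prior count that edgeR adds, so levels or a bound are given instead. The bound sets a single group at 0 UMIs to 3 counts in that group. The share of nuclei in a class has an exact (Clopper-Pearson) 95% binomial interval per library. Intervals and bounds cover counting error only.

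The 19 held-out lists held genes of V(D)J recombination, T cell receptor signalling, selection and activation, egress and trafficking, cytokine receptors and JAK-STAT, thymocyte transcription factors, the Notch pathway, apoptosis, DNA replication, antigen presentation, thymic niche factors, extracellular matrix, clearance and complement, type I interferon response, stress and dissociation, circadian genes, mitochondrial transcripts, W-linked genes and ribosomal proteins. Apart from the 67 ribosomal protein genes, 319 of their members carried a symbol in the files. The members higher or lower were counted with adjustment over all genes tested and adjusted over the list alone. Where no count adjusted over the list alone is given, it was the same. Lists were tested against the other genes with camera (limma 3.58.1) on log-CPM with a preset correlation of 0.01, and again with a correlation estimated from the data, each adjusted over the lists of a contrast. The adjusted p beside a list's count is camera's. Of 180 list results, only DNA replication genes in cycling DP-like and cycling early DN-like nuclei, named partly by cycling markers, passed with both correlations. The named genes were up to 10 per direction with the largest fold among those that passed, moved the same way in both libraries and reached 50 CPM on either side; up to 4 members of each list with the smallest p; and RAG1, RAG2, DNTT, IL7R, CCR7, S1PR1, BCL2, TOX, GATA3 and CD69 in stage contrasts. CD69 was not analysed here. A part of the genes that this rule allows is named in the text. Marker genes are given only as what defines a class. Near-identical copies, such as BF1 and BF2 or BLB1 and BLB2, are named as uncertain. The sample groups, the marker and held-out lists, these tests and the alternative settings were chosen before the data were examined.

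The alternatives were size factors of the DESeq2 type, the DESeq2 1.42.0 Wald test, no filter on low counts, no library block, at least 50 nuclei per library, at least 400 genes per nucleus, called doublets kept, no scaling by library, held-out genes allowed as features, resolution 0.5 and 2, clustering on 70% of the UMIs with testing on the other 30%, and each library left out in turn, with new clusters for shares and the clusters of both libraries for fold changes. Numbered clusters were added to the stage fit after the data were seen. The edgeR fit was tested on data simulated from the means and sizes of these libraries. In the epithelial-like contrast (1941 genes) edgeR recovered 26.5% of 49 genes changed 2-fold and 88.2% of 51 changed 4-fold, with 0% false calls, and in the CD4 SP-like contrast (5414 genes) 24% and 78.4%, with 2.91% false calls. A 2-fold change would often be missed at this depth. These rates cover neither clustering nor contrasts with many changed genes. With 1 group of 2 libraries, no between-group test and no test of outlying samples was possible. Reads, splicing and T cell receptor sequences were not analysed here.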

Results

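Nuclei of chicken (Gallus gallus) thymus, the organ in which T cells mature, were profiled by droplet single-nucleus RNA sequencing, which counts each captured transcript once through a unique molecular identifier (UMI). The 2 libraries came from females at 5 weeks of age and belong to a census of chicken immune organs, so they form 1 group of 2 replicates in which no condition differs. The design allows comparisons between cell classes, and between stages of the T lineage, within libraries. Replicate 1 held 6564 barcodes with 4826743 UMIs in all, and replicate 2 held 6050 barcodes with 6570941 UMIs. After filtering, 4861 nuclei with a median of 661 UMIs and 460 genes remained in replicate 1, and 5239 nuclei with a median of 826 UMIs and 547 genes in replicate 2. The labels do not state separate birds, so p-values measure only how class or stage differences vary between the libraries, which may be technical. Levels below are UMI counts of the nuclei summed per class and library and scaled by the total of that sum to CPM, as mean ± SD over the 2 libraries (n = 2). Fold changes are log2 values ± SE with adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. Gene positions refer to the GRCg7b assembly.

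The thymus libraries consisted almost entirely of T-lineage nuclei. Of the 10100 nuclei analysed, 9588 were T lineage, a share of 94.9% ± 0.320 (SD, n = 2). Thymic epithelial-like nuclei, led by FOXN1 and other epithelial genes, made up 1.63% ± 0.0957 (165 nuclei). B-like nuclei, led by PAX5 and EBF1, made up 1.11% ± 0.0588 (112 nuclei), macrophage-like nuclei, with MARCO among the leading genes, 0.721% ± 0.0598 (73 nuclei), and dendritic-like nuclei, led by PAPPA and FLT3, 0.705% ± 0.0793 (71 nuclei). Erythroid-like nuclei, led by haemoglobin genes, were at 0.501% ± 0.156 (51 nuclei, with 19 in replicate 1, too few to be tested). A further 40 nuclei with markers of more than one class stayed unnamed. The exact (Clopper-Pearson) 95% binomial intervals of the 2 libraries overlapped for every class, from 94.5% to 95.8% in replicate 1 and 94.1% to 95.3% in replicate 2 for the T lineage. Like all intervals here they cover counting error only. A minimum of 400 genes per nucleus in place of 200 raised the share of epithelial-like nuclei to 2.18% and that of B-like nuclei to 1.52%.

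Within the T lineage, nuclei with the features of double positive (DP) thymocytes, which carry both CD4 and CD8, were the largest stage. DP-like nuclei made up 31.0% ± 4.98 of T-lineage nuclei (2986 nuclei) and cycling DP-like nuclei 16.1% ± 2.64 (1537 nuclei). γδ-like nuclei, led by SOX13, made up 6.69% ± 0.170 (642 nuclei), CD4 single positive-like (CD4 SP-like) nuclei 5.24% ± 0.289 (502 nuclei), cycling early double negative-like (early DN-like) nuclei 3.52% ± 0.357 (338 nuclei) and cycling γδ-like nuclei 3.41% ± 1.11 (324 nuclei). The remaining 34.0% fell into 5 clusters to which the fixed markers gave no name. The libraries differed beyond counting error in DP-like nuclei, at 27.5% (exact 95% interval 26.2% to 28.8%) in replicate 1 and 34.5% (33.2% to 35.9%) in replicate 2, in cycling DP-like nuclei, at 17.96% (16.9% to 19.1%) and 14.2% (13.3% to 15.2%), and in cycling γδ-like nuclei, at 4.19% (3.63% to 4.81%) and 2.62% (2.19% to 3.10%). These shares varied with the settings. γδ-like nuclei made up 17.2% when replicate 2 was left out and 0.717% when called doublets were kept, which put cycling γδ-like nuclei at 9.33%. Cycling DP-like nuclei made up 6.17% and cycling γδ-like nuclei 1.81% when replicate 1 was left out, and CD4 SP-like nuclei 9.68% at a coarser clustering.

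**Figure D1:**
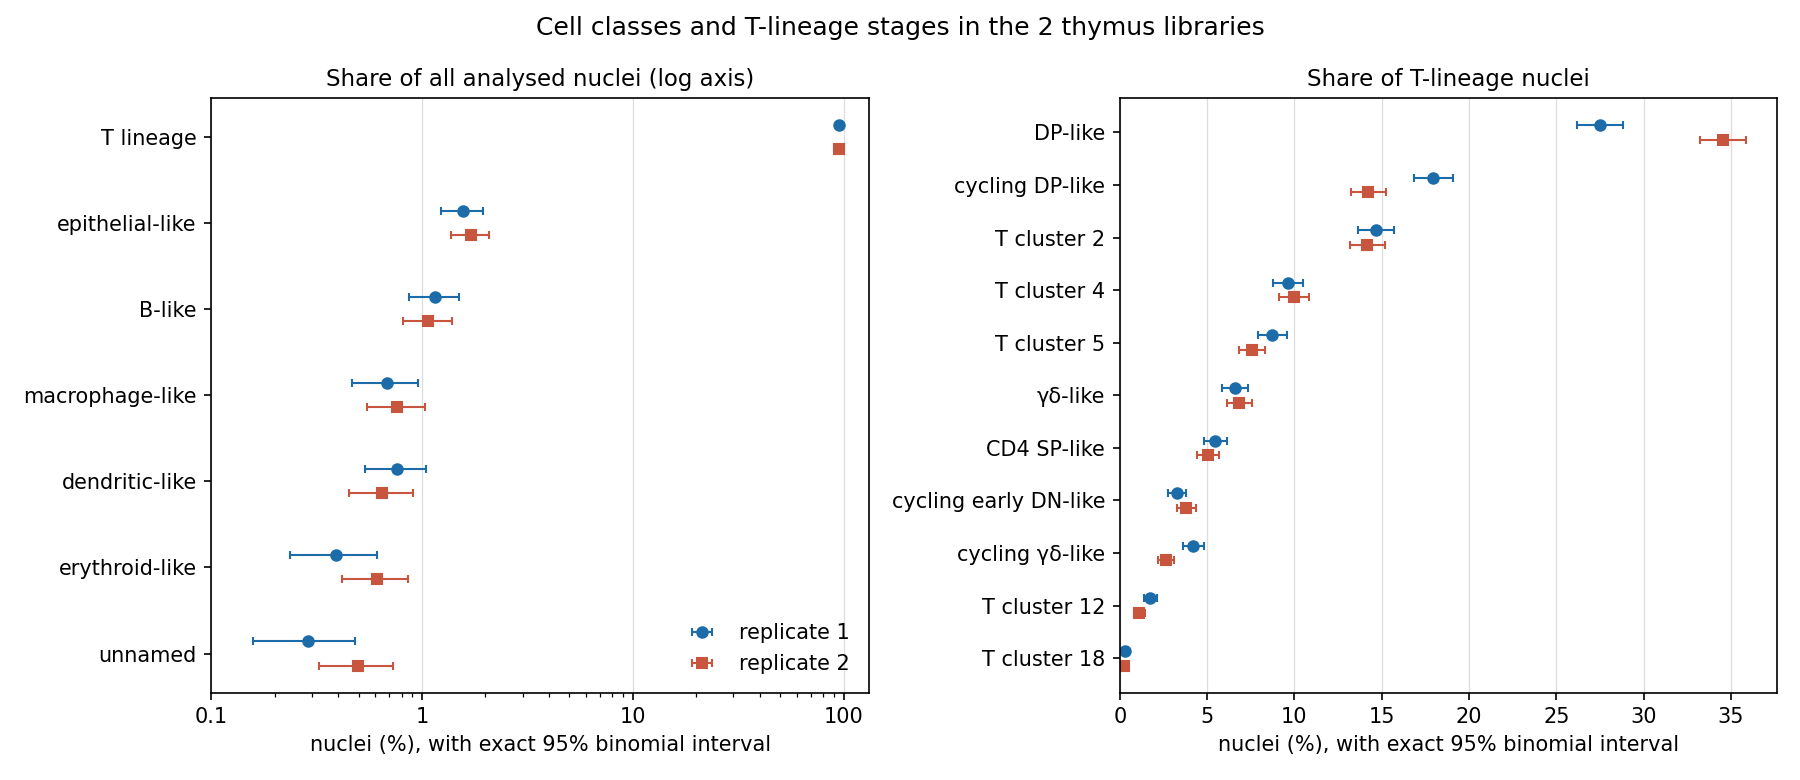
Share of nuclei in each cell class (left, % of all analysed nuclei, log axis) and in each T-lineage stage or numbered cluster (right, % of T-lineage nuclei, linear axis) in replicate 1 (circles) and replicate 2 (squares), with exact 95% binomial intervals. T-lineage nuclei lie near 95% in both libraries, and DP-like nuclei at 27.5% and 34.5%.

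The first set of comparisons asked which genes set each class apart from the mean of the other classes tested, over 2628 genes that had not been used for clustering. Erythroid-like nuclei are not among these. T-lineage nuclei held higher levels of DNTT, RAG1, TRAT1 and GRAP2, and a lower level of CD74, the invariant chain of major histocompatibility complex (MHC) class II. DNTT, which encodes terminal deoxynucleotidyl transferase and lies at chromosome 6 from 21976196 to 22086355, stood at 2182 ± 305 CPM in T-lineage nuclei and 45.8 ± 64.7 CPM in the others, where its 18 UMIs all lay in dendritic-like nuclei of 1 library (erythroid-like nuclei held 10 and 52). RAG1, a subunit of the recombinase (chromosome 5, 19040483 to 19050348), was at 347 ± 16.2 CPM with 0 UMIs in the other classes tested (7 in erythroid-like nuclei). The adaptor gene TRAT1 stood at 588 ± 1.56 CPM against 2 UMIs elsewhere, and GRAP2, an adaptor downstream of the receptor, at 1590.5 ± 94.4 against 32.1 ± 16.9 CPM (adjusted p = 8.15e-08). In the other direction CD74 (chromosome 13, 12750532 to 12754143) was at 4.16 ± 1.40 against 1187 ± 269 CPM (adjusted p = 1.81e-08).

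In all, 756 genes passed in the T lineage, 498 higher and 258 lower. Among the 13 T cell receptor signalling genes tested, 10 were higher and 3 did not pass, with 11 higher when adjusted over the list alone. THEMIS, needed for thymocyte selection, was at 1196 ± 73.6 against 148 ± 14.8 CPM, and LCP2, which encodes the adaptor SLP-76, at 801 ± 7.77 against 251 ± 42.98 CPM. This list stood apart from the other genes by camera (adjusted p = 6.57e-05), but not with an estimated correlation (adjusted p = 0.130). Thymocyte transcription factors were higher for 13 of 20 and did not pass for the other 7 (adjusted p = 9.02e-04, or 0.105 with an estimated correlation). GATA3 (chromosome 1, 5010557 to 5039662), a regulator of T cell commitment, was at 464 ± 8.88 against 69.02 ± 9.61 CPM, ETS1 at 1829 ± 65.5 against 227 ± 30.2 CPM, the E protein gene TCF3 at 1004 ± 84.4 against 64.9 ± 15.2 CPM, and TOX at 741 ± 69.7 against 294 ± 31.5 CPM. V(D)J recombination genes were higher for 3 of 4 (adjusted p = 0.0188, or 0.219 with an estimated correlation). PRKDC, the DNA-dependent protein kinase, was at 249 ± 11.5 against 259.8 ± 42.3 CPM and did not pass. Antigen presentation genes were lower for 7 of 12 and higher for 1 (adjusted p = 2.03e-05, or 0.105 with an estimated correlation). Clearance genes were lower for 3 of 12, or 4 adjusted over the list alone (adjusted p = 0.00117, adjusted p = 0.105 with an estimated correlation), among them the lysosomal protease CTSD (19.7 ± 7.69 against 433 ± 9.47 CPM). Interferon response genes were lower for 2 of 5, or 3 adjusted over the list alone (adjusted p = 0.0329, adjusted p = 0.320 with an estimated correlation), and extracellular matrix genes for 2 of 6 (adjusted p = 0.0147, adjusted p = 0.146 with an estimated correlation). The niche factor list passed camera as lower (adjusted p = 0.0273, adjusted p = 0.173 with an estimated correlation) although each of its 5 genes missed the threshold. BCL2, which protects cells from death (chromosome 2, 67578119 to 67668149), was at 1274 ± 6.79 against 674 ± 72.05 CPM (adjusted p = 0.00963), and HINTW, a gene of the female-specific W chromosome, at 688 ± 64.1 against 266 ± 67.8 CPM (adjusted p = 7.05e-04). The contrast averages classes on the log scale, so a class at 0 UMIs weighs heavily. A mean CPM lower than elsewhere was found for 21 of the 498 genes called higher here, such as HSPA8 (165 ± 12.6 against 190.4 ± 69.6 CPM), and for 2 in B-like, 2 in dendritic-like, 11 in macrophage-like and 37 in epithelial-like nuclei. The number of calls was 1399 with no filter on low counts, 455 when clusters and tests used separate UMIs and, with other classes in the reference, 469 with called doublets kept and 391 at a finer clustering. By DESeq2, RAG1 and TRAT1 had an adjusted p of 0.104 and 0.0864. The call of BCL2 was lost under 2 alternative settings and those of CTSD and HSPA8 under 1 each.

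B-like nuclei held higher levels of SYK, ARHGAP15 and NFATC1. SYK, the tyrosine kinase downstream of the B cell receptor, stood at 306 ± 21.9 CPM against 54.9 ± 29.7 CPM in the mean of the other classes (adjusted p = 3.80e-04). ARHGAP15, a Rac-specific GTPase-activating protein of haematopoietic cells, was at 3279 ± 1.90 against 867 ± 64.7 CPM (adjusted p = 1.52e-06), and NFATC1, a calcium-regulated transcription factor, at 1024 ± 174 against 84.1 ± 25.4 CPM (adjusted p = 4.37e-05). At the other end, SH3PXD2A, a scaffold of invasive adhesions, had 0 UMIs in B-like nuclei against 507 ± 18.99 CPM, at least 23.6-fold lower over a floor of 3 counts in the group, and ARHGAP32 and PTPN13 were also at 0 UMIs.

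Of 289 genes that passed in B-like nuclei, 212 were higher and 77 lower. The antigen presentation list was higher for 6 of 12, or 7 adjusted over the list alone (adjusted p = 1.84e-04, adjusted p = 0.159 with an estimated correlation). CD74 was at 1168 ± 14.8 against 896 ± 272 CPM and the class II beta chain gene BLB1 (chromosome 16, 2185532 to 2187356) at 742 ± 479 against 470.1 ± 307 CPM. BLB1 and BLB2 (chromosome 16, 2192787 to 2194303) are near-identical copies between which counting could split reads, and their levels varied widely between the libraries. Thymocyte transcription factors were higher for 9 of 20, or 10 adjusted over the list alone (adjusted p = 0.00788, adjusted p = 0.159 with an estimated correlation). They included the lymphoid factors IKZF3 (717 ± 77.7 against 187 ± 3.87 CPM) and IKZF1 (1049 ± 44.8 against 444 ± 9.20 CPM), both used in B cells as well. Of the T cell receptor signalling list 5 of 13 were higher, or 6 adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.334 with an estimated correlation), among them the phosphatase PTPN6 (387 ± 92.3 against 174 ± 67.7 CPM), which also acts in B cells. S1PR1, the sphingosine-1-phosphate receptor through which lymphocytes leave tissues (chromosome 8, 11401083 to 11453311), was at 551 ± 94.1 against 96.9 ± 47.9 CPM (adjusted p = 3.66e-04). Trafficking genes were higher for 3 of 6 and lower for 1 (adjusted p = 0.280). The lower genes included MAML3, a Notch coactivator, at 70.9 ± 8.91 against 881 ± 63.4 CPM (adjusted p = 1.64e-04), and ABCA1, a cholesterol exporter, at 195 ± 112 against 1072 ± 62.8 CPM, the 1 of 12 clearance genes that was lower (adjusted p = 0.00788, adjusted p = 0.159 with an estimated correlation). HSP90AA1, a chaperone of the stress list, was at 343 ± 5.84 against 544 ± 12.3 CPM (adjusted p = 0.0359), a call lost under 6 of 9 alternative settings. Those of ABCA1 and PTPN13 were lost under 2 and those of SH3PXD2A and BLB2 under 1. Niche factors passed camera as lower (adjusted p = 0.0322, or 0.243 with an estimated correlation) although its 5 genes all missed the threshold. BCL2 did not pass, at 1039 ± 14.4 against 733 ± 70.1 CPM. DESeq2 called 460 genes in place of 289.

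Dendritic-like nuclei had the highest mean levels of the class II genes CD74, BLB1 and BLB2 among the 5 classes tested. CD74 stood at 2289.7 ± 848 CPM against 616 ± 56.6 CPM (adjusted p = 2.16e-06), BLB2 at 2129.9 ± 2023 against 396 ± 281 CPM and BLB1 at 1459.9 ± 1158 against 291 ± 138 CPM, with SDs that show how far the libraries lay apart and the same doubt about near-identical copies. SMOC2, a matricellular protein gene, was at 412 ± 35.8 against 0.348 ± 0.418 CPM (adjusted p = 4.75e-04), and ARHGAP22 at 364 ± 61.05 against 11.9 ± 7.24 CPM (adjusted p = 3.95e-04). RBPJ, the DNA-binding partner of Notch, was at 1132 ± 241 against 209.6 ± 4.40 CPM (adjusted p = 6.75e-04). NUAK1, a kinase gene, had 1 UMI in these nuclei against 533 ± 40.8 CPM in the other classes (adjusted p = 6.75e-04).

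The test called 223 genes in dendritic-like nuclei, 200 higher and 23 lower. Genes of antigen presentation were higher for 4 of 12, or 6 adjusted over the list alone (adjusted p = 0.00126, adjusted p = 0.193 with an estimated correlation), including DMB2, the beta chain of the class II peptide exchange factor (239 ± 7.78 against 89.4 ± 40.9 CPM). Interferon response genes were higher for 2 of 5, or 4 adjusted over the list alone (adjusted p = 0.00707, adjusted p = 0.327 with an estimated correlation), with EPSTI1 at 764 ± 215 against 177 ± 53.6 CPM. The extracellular matrix list passed camera as lower (adjusted p = 0.00155, adjusted p = 0.193 with an estimated correlation) although all 6 of its genes missed the threshold. Transcription factors went both ways, with 4 of 20 higher and 1 lower (adjusted p = 0.637). The factor RUNX3 was at 1304 ± 113 against 409 ± 95.6 CPM (adjusted p = 6.27e-04), ZEB1 at 1898 ± 325 against 569 ± 20.1 CPM (adjusted p = 5.40e-04) and ID2, which blocks E proteins, at 358 ± 276 against 30.3 ± 10.4 CPM (adjusted p = 0.0262), while NFATC1 fell to 2 UMIs. Selection and activation genes were higher for 3 of 7, or 4 adjusted over the list alone (adjusted p = 0.110), among them NFKB1 (704 ± 213 against 263 ± 41.1 CPM) and its inhibitor NFKBIA (439.6 ± 161 against 179.9 ± 9.16 CPM). Cytokine receptor and JAK-STAT genes were higher for 2 of 12, or 4 adjusted over the list alone (adjusted p = 0.108), with the kinase JAK2 at 644 ± 211 against 231 ± 32.1 CPM. The cholesterol exporter ABCG1 was at 85.8 ± 80.1 against 431 ± 27.1 CPM (adjusted p = 0.0159), SESN1, a stress-induced regulator of growth signalling, at 93.2 ± 74.3 against 558 ± 44.6 CPM (adjusted p = 0.00976), and HINTW at 111 ± 73.9 against 410.5 ± 65.3 CPM (adjusted p = 0.0378). DNTT was called higher from 18 UMIs of 1 library and had a lower mean CPM than elsewhere (183 ± 259 against 546 ± 76.4 CPM). With replicate 2 left out it had 0 UMIs there. Its call was lost under 3 of 6 alternative settings, those of JAK2, NFKB1 and HINTW under 2 and those of NFKBIA and NFATC1 under 1. DESeq2 called 350 genes in place of 223, and separate UMIs for clustering and testing left 111. No dendritic-like class was found with called doublets kept or at a coarser clustering.

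Macrophage-like nuclei held higher levels of SLC40A1, C1QC and STAB1. SLC40A1, the iron exporter ferroportin, stood at 1278 ± 384 CPM against 6.83 ± 2.05 CPM (adjusted p = 1.22e-07). C1QC, a chain of complement component C1q, was at 257 ± 10.9 CPM against 3 UMIs in the other classes (adjusted p = 3.10e-04, but 0.111 by DESeq2), and STAB1, a scavenger receptor, at 731 ± 51.9 against 11.9 ± 3.36 CPM (adjusted p = 5.10e-06). CTSD was at 1476 ± 28.00 against 69.2 ± 14.5 CPM (adjusted p = 3.39e-06) and ABCA1 at 2926 ± 57.02 against 389.8 ± 76.6 CPM (adjusted p = 5.10e-06).

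Of the 12 clearance and complement genes tested, 10 were higher and 2 did not pass, of which 1 was lower when adjusted over the list alone (camera adjusted p = 3.27e-07, adjusted p = 0.0686 with an estimated correlation). The whole test called 382 genes, 318 higher and 64 lower. MAOA, a monoamine oxidase, was at 324 ± 196 CPM against 1 UMI elsewhere, the protease gene FAP at 589 ± 27.7 against 9.86 ± 6.67 CPM (adjusted p = 8.33e-06), and the chemerin receptor CMKLR1 at 275 ± 14.2 against 2.57 ± 3.63 CPM (adjusted p = 1.15e-04). Antigen presentation genes were higher for 4 of 12 (adjusted p = 0.0842). CTSH, a lysosomal protease, was at 452 ± 40.4 against 94.3 ± 4.92 CPM, and CD74 at 1024 ± 138 against 932 ± 234 CPM. Interferon response genes were higher for 3 of 5 (adjusted p = 0.0558), with IRF7 at 217 ± 45.2 against 86.7 ± 6.58 CPM. Of the matrix list 2 of 6 were higher, the metalloproteinase inhibitors TIMP3 (288 ± 70.8 against 49.6 ± 18.5 CPM) and TIMP2 (262 ± 32.97 against 25.3 ± 12.7 CPM), while the list as a whole lay lower (adjusted p = 0.313). IL15, a cytokine gene of the niche list, was at 293 ± 115 against 61.4 ± 8.23 CPM (adjusted p = 1.43e-04) and the only one of its 5 tested genes to pass. Transcription factors of the lymphoid list were lower for 3 of 20, or 4 adjusted over the list alone (adjusted p = 0.234): BACH2 was at 107 ± 75.9 against 886 ± 41.2 CPM, ETS1 at 79.7 ± 37.1 against 664 ± 55.8 CPM and ZEB1 at 324 ± 45.9 against 962 ± 113 CPM. IKZF2 was at 111 ± 44.6 against 617 ± 53.00 CPM (adjusted p = 0.00167), BCL2 at 307 ± 246 against 916 ± 135 CPM (adjusted p = 0.0423), and TGFBR2, a TGF-β receptor, fell to 2 UMIs. The splicing factor gene SRSF3 and the amino acid transporter gene SLC38A2, used by most cells, were listed at 0 UMIs in these 73 nuclei. With separate UMIs for clustering and testing 198 genes were called. The calls of ETS1, BCL2 and SRSF3 were lost under 4, 3 and 3 of the alternative settings, that of ZEB1 under 2 and those of IRF7, IKZF2 and TGFBR2 under 1 each.

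Epithelial-like nuclei had the most genes called among the 5 classes tested. CXCL12, a chemokine that attracts thymocyte progenitors (chromosome 6, 19780250 to 19797382), was at 1274 ± 117 CPM against 0 UMIs in the other classes. DLL4, the Notch ligand that directs progenitors to the T lineage (chromosome 5, 23929187 to 23940408), was at 628 ± 106 against 8.95 ± 7.95 CPM (adjusted p = 2.39e-08). ARHGAP15 was at 0 UMIs against 1686 ± 65.1 CPM, at least 301-fold lower, and IQGAP2, DOCK8, LCP1 and ITGA4, which act in leukocyte movement and adhesion, were at 0 UMIs too. Of 2628 genes tested, 1495 passed, 780 higher and 715 lower.

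All 5 niche factors tested were higher (camera adjusted p = 0.00806, adjusted p = 0.257 with an estimated correlation). They included VEGFC, a growth factor for lymphatic vessels (257 ± 21.8 against 4.26 ± 4.98 CPM), and IL15 (239 ± 41.7 against 75.00 ± 30.9 CPM). Extracellular matrix genes were higher for 4 of 6, but the list missed the threshold of camera (adjusted p = 0.0577, adjusted p = 0.275 with an estimated correlation). The laminin genes LAMA2 and LAMB1 were at 386 ± 0.438 against 5.67 ± 3.40 CPM and 176 ± 38.8 against 16.7 ± 4.01 CPM. COL18A1, a basement membrane collagen, was at 212 ± 11.9 CPM against 3 UMIs. RAB39A, a vesicle transport GTPase, was at 856 ± 63.8 CPM and OCM1, a parvalbumin-like calcium-binding protein, at 427 ± 27.8 CPM, both with 0 UMIs elsewhere. Stress genes were higher for 3 of 6 and lower for 2 (adjusted p = 0.521), with the chaperone HSPH1 at 996 ± 63.1 against 49.8 ± 11.7 CPM (adjusted p = 3.00e-09) and HSPA5 at 15.02 ± 9.09 against 434 ± 88.9 CPM (adjusted p = 1.69e-06). IL6ST, the shared receptor of the interleukin-6 family, was at 323 ± 9.22 against 95.9 ± 17.9 CPM (adjusted p = 2.06e-05), ABCG1 at 844 ± 41.4 against 242 ± 17.4 CPM (adjusted p = 1.03e-06) and the circadian gene CRY2 at 268 ± 22.7 against 84.8 ± 10.6 CPM. Circadian genes were higher for 2 of 3 (adjusted p = 0.430). T cell receptor signalling genes were lower for 9 of 13 (adjusted p = 0.00267, adjusted p = 0.275 with an estimated correlation) and thymocyte transcription factors for 14 of 20, with 1 higher (adjusted p = 0.00806, adjusted p = 0.257 with an estimated correlation). The kinase FYN was at 23.8 ± 10.9 against 826 ± 60.1 CPM and RUNX3 at 29.9 ± 34.7 against 728 ± 115 CPM, while IKZF1 fell to 3 UMIs. Of the antigen presentation genes 1 of 12 was higher, a call lost when adjusted over the list alone, and 4 were lower (adjusted p = 0.385). The chaperone CALR was at 7.16 ± 10.1 against 259.8 ± 175 CPM. Genes used by most cells, such as HMGB1, HSPA8 and PHF2, were also listed at 0 UMIs in these nuclei, and 166 of the 715 genes called lower were at 0. The number of calls rose to 2671 with no filter on low counts and 2550 when each class needed at least 50 nuclei per library, and fell to 602 with separate UMIs for clustering and testing.

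The second set of comparisons asked how the named stages of the T lineage differ from DP-like nuclei, over 6028 genes. Among the genes fixed in advance, RAG1, RAG2 and DNTT were highest in DP-like nuclei of the 6 named stages, at 1143 ± 121, 405 ± 68.1 and 4737 ± 384 CPM. IL7R, CCR7 and S1PR1, receptors for interleukin-7, for chemokines of the thymic medulla and for the exit signal, were below 10 CPM there. DP-like nuclei were also the shallowest named stage, with medians of 482.5 and 603 UMIs, and 95 of the genes tested had 0 UMIs in all 2986 of them. The 5 heat-shock genes HSPA8, HSP90AA1, HSPH1, HSPD1 and DNAJA1 summed to 44.0 ± 4.40 CPM in DP-like nuclei and 785 ± 237 CPM in CD4 SP-like nuclei, and this low reference level enters every result for the stress list below.

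**Figure D2:**
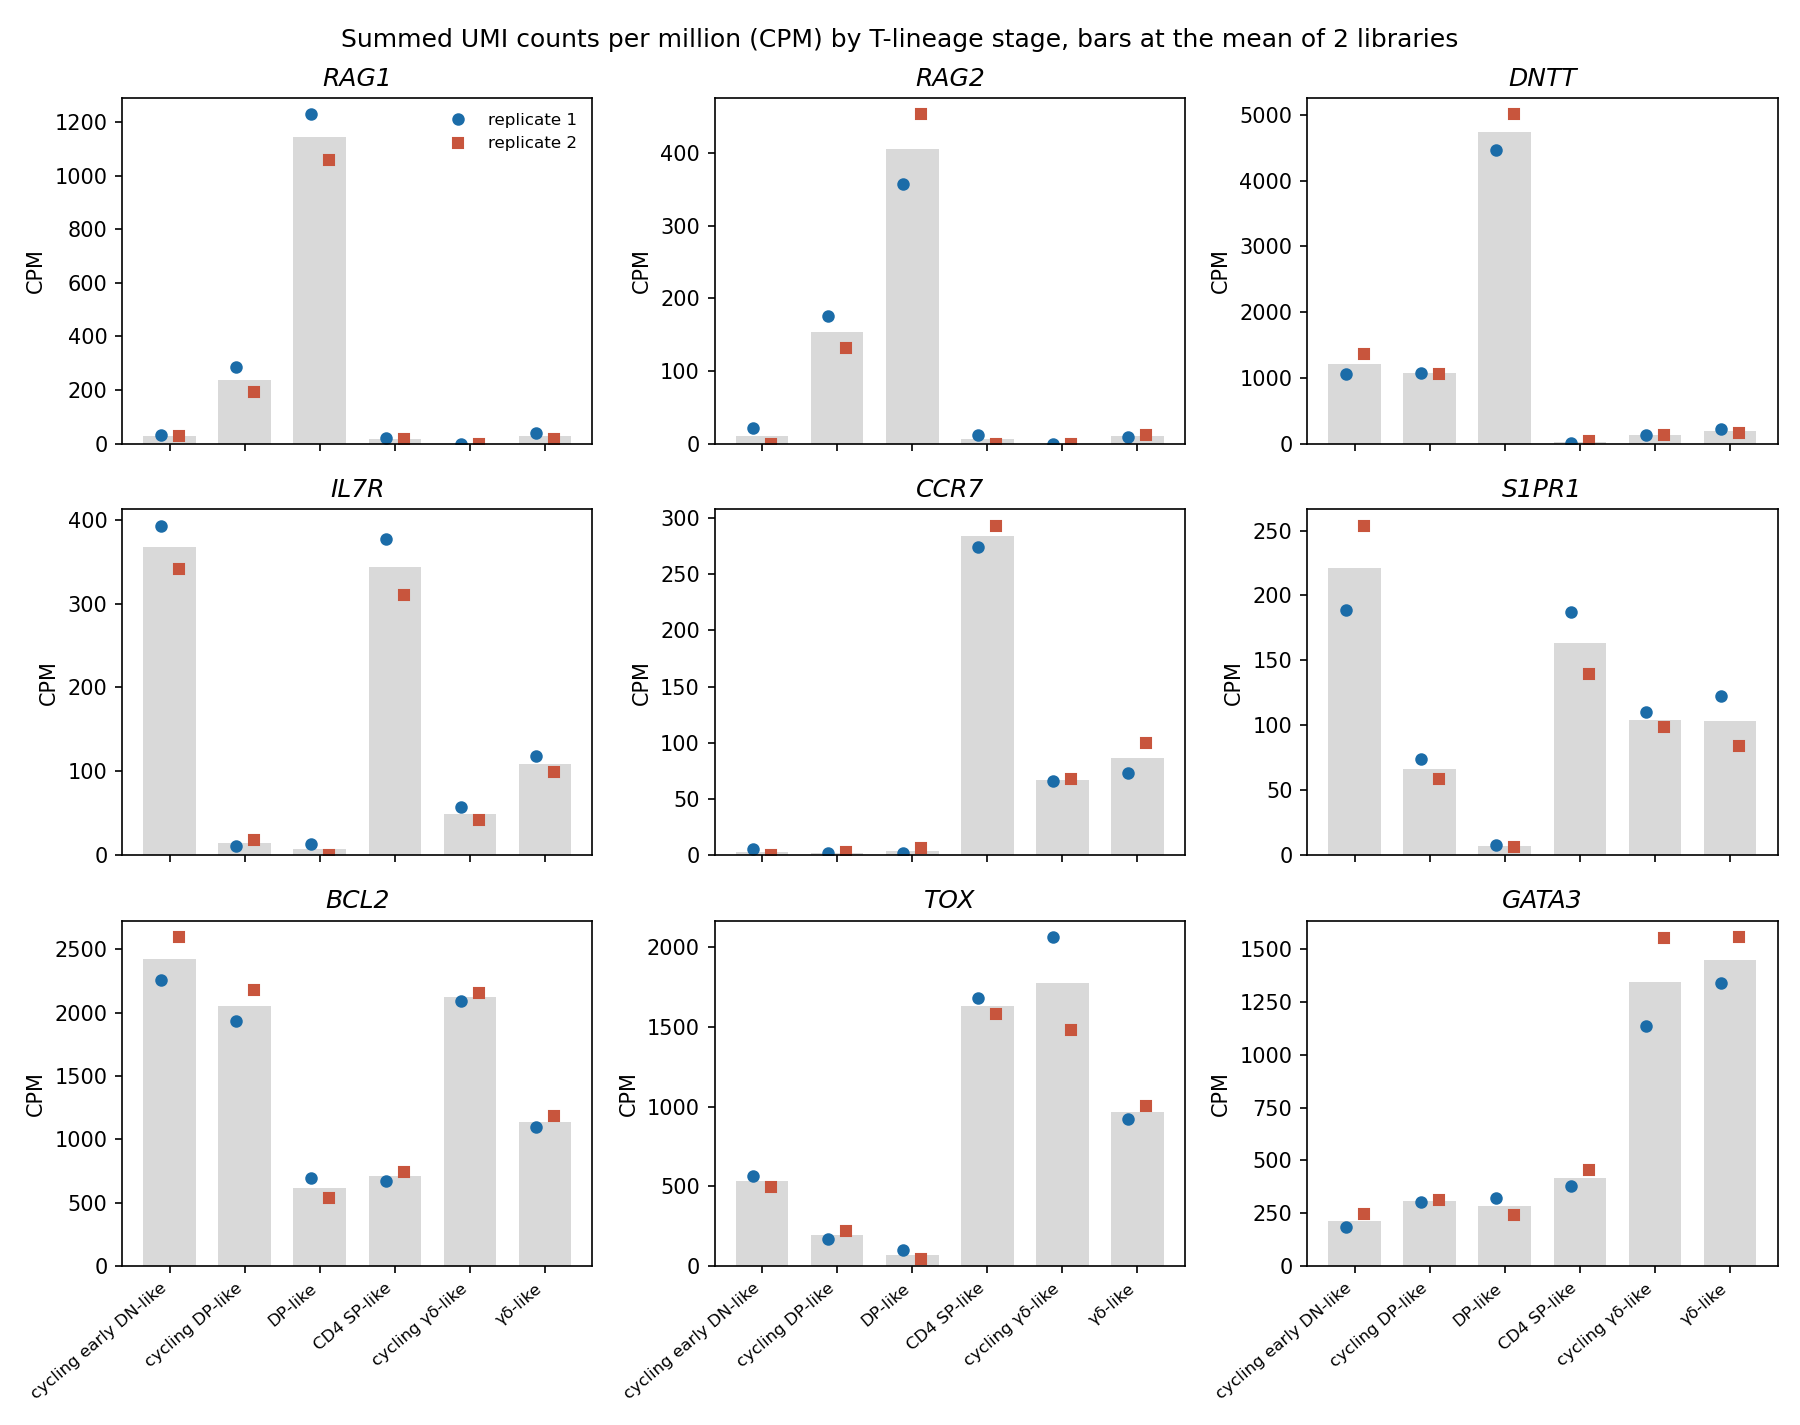
Level (CPM, linear axes from 0) of 9 genes fixed in advance in the 6 named T-lineage stages, with replicate 1 as circles, replicate 2 as squares and the mean as bars. RAG1, RAG2 and DNTT are highest in DP-like nuclei, CCR7 in CD4 SP-like nuclei at 284 CPM, and BCL2 in early DN-like nuclei at 2427 CPM.

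CD4 SP-like nuclei held little RAG1, RAG2 and DNTT and higher levels of CCR7, IL7R and S1PR1 than DP-like nuclei. RAG1 was at 17.9 ± 1.63 CPM against 1143 ± 121 CPM in DP-like nuclei, a log2 fold change of -6.17 ± 0.27 (adjusted p = 3.38e-08), and DNTT at 23.4 ± 22.3 against 4737 ± 384 CPM (-7.72 ± 0.28, adjusted p = 2.38e-09). CCR7 (chromosome 27, 4466688 to 4475421) was higher by 5.82 ± 0.51 (284 ± 13.3 against 3.85 ± 3.36 CPM, adjusted p = 4.45e-06), IL7R (chromosome Z, 11442771 to 11458044) by 5.77 ± 0.58 (344 ± 47.7 against 6.63 ± 9.38 CPM, adjusted p = 1.36e-05) and S1PR1 by 4.34 ± 0.38 (adjusted p = 4.98e-06). TOX, a nuclear factor required for CD4 lineage development (chromosome 2, 111854653 to 112074874), was higher by 4.38 ± 0.26 (1628 ± 70.3 against 72.04 ± 37.7 CPM, adjusted p = 1.82e-07). GATA3 and BCL2 did not pass, at 418 ± 52.3 against 284 ± 56.8 CPM and 708 ± 52.8 against 618 ± 113 CPM.

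In CD4 SP-like nuclei 1420 genes passed, 826 higher and 594 lower. V(D)J recombination genes were lower for 4 of 10 and higher for 1 (camera adjusted p = 0.00482, adjusted p = 0.108 with an estimated correlation). LIG4, the ligase that joins cut ends, had 0 UMIs against 141 ± 6.88 CPM, at least 29.2-fold lower over a floor of 3 counts in the group, and RAG2 had 3 UMIs against 405 ± 68.1 CPM. Interferon response genes were higher for 6 of 9 (adjusted p = 3.96e-04, adjusted p = 0.108 with an estimated correlation). EPSTI1 was at 198 ± 27.3 CPM and OASL at 59.3 ± 3.01 CPM, both with 0 UMIs in DP-like nuclei, at least 119-fold and 35.6-fold higher, and IRF1 was higher by 4.93 ± 0.89. Genes of antigen presentation were higher for 6 of 10 and lower for 1, or 8 higher adjusted over the list alone (adjusted p = 9.68e-04, adjusted p = 0.108 with an estimated correlation). BF1, an MHC class I heavy chain whose near-identical copy BF2 makes its count uncertain (chromosome 16, 2213458 to 2216245), was at 97.7 ± 35.7 CPM against 1 UMI, and the peptide transporter gene TAP2 was higher by 2.54 ± 0.35, while CALR was lower by a log2 change of -1.23 ± 0.23. Stress and heat-shock genes were higher for 5 of 7 and lower for 1 (adjusted p = 0.0104, adjusted p = 0.406 with an estimated correlation). HSP90AA1 was higher by 3.44 ± 0.25. Selection and activation genes were higher for 6 of 12 and lower for 2, or 3 lower adjusted over the list alone (adjusted p = 0.154), with EGR3, induced by receptor signals, higher by 3.52 ± 0.65, NFKB1 by 1.56 ± 0.31, and the Ikaros family member IKZF2 at -1.86 ± 0.24. Without TMM scaling, IKZF2 had -1.10 with replicate 2 left out, and CALR had -0.80 with replicate 1 left out.

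T cell receptor signalling genes went both ways in CD4 SP-like nuclei, with 9 of 18 higher and 5 lower (adjusted p = 0.375). UBASH3A, a brake on receptor signalling, was higher by 3.95 ± 0.35, whereas SLA, an adaptor that lowers receptor levels on DP thymocytes, had -3.13 ± 0.24 and GRAP2 -2.23 ± 0.14. Transcription factors were higher for 9 of 25 and lower for 5, or 6 lower adjusted over the list alone (adjusted p = 0.385). The repressor gene BACH2 was higher by 2.09 ± 0.15 and ID2 had 0 UMIs in DP-like nuclei, while TCF3, the E protein that ID2 opposes, had -3.20 ± 0.19 and MYB -2.48 ± 0.21. Notch pathway genes were higher for 5 of 13 and lower for 3, or 6 and 4 adjusted over the list alone (adjusted p = 0.991), with the Notch-modifying glycosyltransferase LFNG higher by 5.45 ± 0.91 and the coactivator MAML2 at -2.89 ± 0.22. Apoptosis genes were higher for 2 of 10 and lower for 2 (adjusted p = 0.991): CASP8, the caspase of death receptors, was higher by 4.64 ± 0.48, the pro-apoptotic gene BMF had -4.40 ± 0.51, and BCL2L1, a survival gene of DP thymocytes, fell to 2 UMIs against 328 ± 32.2 CPM. Trafficking genes were higher for 4 of 10 and lower for 1 (adjusted p = 0.417), cytokine receptor and JAK-STAT genes for 4 of 20 and 1, or 7 higher adjusted over the list alone (adjusted p = 0.196), with TGFBR2 higher by 1.61 ± 0.15. DNA replication genes were higher for 3 of 27 and lower for 2 (adjusted p = 0.385), circadian genes for 1 of 8 and 3 (adjusted p = 0.375), with ARNTL at -1.77 ± 0.24, and clearance genes for 1 of 7 and 3 (adjusted p = 0.245), with ABCA1 at -3.21 ± 0.30. The 6 ribosomal protein genes tested (adjusted p = 0.991), the 1 mitochondrial transcript tested, ATP6 (27.95 ± 19.8 against 5.89 ± 8.33 CPM), and HINTW (676 ± 12.1 against 623 ± 62.4 CPM) did not pass. Of the genes with the largest folds, KCNK7, a potassium channel gene, was at 120.1 ± 51.3 CPM and GALC, a lysosomal enzyme, at 104 ± 9.06 CPM with 0 UMIs in DP-like nuclei, and TMEM120A had 0 UMIs against 178 ± 1.90 CPM. At the coarser clustering, 6 genes were called in the opposite direction, among them IKZF2 with a log2 fold change of 1.23.

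Cycling DP-like nuclei held higher levels of POLA1 and UHRF1 and lower levels of RAG1, RAG2 and DNTT than DP-like nuclei. POLA1, the catalytic subunit of DNA polymerase alpha, was higher by 3.73 ± 0.18 (1282 ± 120.0 against 84.9 ± 19.5 CPM, adjusted p = 6.09e-08), and UHRF1, which maintains DNA methylation at replication, by 2.82 ± 0.13 (1255 ± 63.00 against 153 ± 0.761 CPM, adjusted p = 6.09e-08). RAG1 was at 238 ± 65.2 CPM (-2.50 ± 0.18, adjusted p = 1.46e-06), RAG2 at 154 ± 31.2 CPM (-1.64 ± 0.38, adjusted p = 0.00723) and DNTT at 1073 ± 10.3 CPM (-2.36 ± 0.17, adjusted p = 1.23e-06). BCL2 was higher by 1.52 ± 0.14 (adjusted p = 7.09e-06), TOX by 1.32 ± 0.27 (adjusted p = 0.00335) and S1PR1 by 3.02 ± 0.39 (adjusted p = 1.02e-04). GATA3, IL7R and CCR7 did not pass, at 309 ± 6.38, 14.5 ± 5.36 and 1.82 ± 0.670 CPM.

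In cycling DP-like nuclei 1616 genes passed, 1032 higher and 584 lower. DNA replication genes were higher for 23 of 27, or 24 adjusted over the list alone. Camera gave adjusted p = 7.74e-13, or 0.0308 with an estimated correlation. Cycling markers named the cycling stages, so this test was not independent. E2F1, a driver of S phase entry, was higher by 2.63 ± 0.29, and RRM2, a subunit of ribonucleotide reductase, stood at 165 ± 22.9 CPM against 3 UMIs. Among the largest folds, INCENP, which encodes a chromosomal passenger protein, was at 510.5 ± 102 against 2.65 ± 2.50 CPM, FOXM1 at 260.5 ± 28.3 CPM against 1 UMI, and the kinase gene PLK1 at 77.8 ± 9.60 CPM and the kinetochore gene CENPN at 97.2 ± 3.04 CPM against 0 UMIs, at least 46.7-fold and 58.4-fold higher. Stress genes were higher for 5 of 7 and lower for 1 (adjusted p = 0.0185, adjusted p = 0.398 with an estimated correlation), with HSP90AA1 higher by 4.45 ± 0.24 and the antiproliferative gene BTG2 at -4.95 ± 0.53 (8.31 ± 6.06 against 219 ± 5.82 CPM). T cell receptor signalling genes were lower for 8 of 18 and higher for 2, or 9 lower adjusted over the list alone (adjusted p = 0.00453, adjusted p = 0.217 with an estimated correlation). SLA had -1.995 ± 0.20, the kinase gene PRKCQ -1.68 ± 0.16 and PLCG1, a phospholipase of the receptor pathway, -1.24 ± 0.16. V(D)J recombination genes were lower for 3 of 10 and higher for 2 (adjusted p = 0.270), the latter being HMGB1 (2.95 ± 0.33), a DNA-bending cofactor of the recombinase, and XRCC4 (2.56 ± 0.41), the partner of LIG4. Transcription factors were higher for 2 of 25 and lower for 10, or 7 and 13 adjusted over the list alone (adjusted p = 0.0974), with CBFB, the partner of RUNX factors, higher by 2.39 ± 0.21, and RUNX3 (-1.26 ± 0.15) and FOXP1 (-0.70 ± 0.10) lower. Lower genes also included MAML2 (-2.63 ± 0.21), the histone demethylase gene KDM5B (-4.08 ± 0.32), BMF (-2.71 ± 0.38), and the cholesterol exporters ABCA1 (-2.80 ± 0.26) and ABCG1 (-2.75 ± 0.33). The antigen presentation list was higher for 2 of 10 (adjusted p = 0.959) and interferon response genes for 1 of 9 (adjusted p = 0.896). HINTW was lower (-0.62 ± 0.11, adjusted p = 0.00155), as was 1 of the 6 ribosomal protein genes tested, RPL34 (-2.11 ± 0.41). With replicate 2 left out TOX had 0.76, RAG2 -1.02, XRCC4 4.32 and HINTW -0.41, and with replicate 1 left out TOX had 2.27, FOXP1 -0.45 and HINTW -0.40. No separate cycling DP-like stage was found with called doublets kept, nor at either other clustering resolution.

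Cycling early DN-like nuclei differed from DP-like nuclei by the most genes among the 5 stages tested, 2057 in all, of which 1187 were higher and 870 lower. HMGB1 stood at 2379.5 ± 197 against 73.1 ± 21.6 CPM (4.80 ± 0.34, adjusted p = 5.12e-07), IL7R at 367 ± 36.7 against 6.63 ± 9.38 CPM (5.80 ± 0.58, adjusted p = 9.41e-06) and S1PR1 at 221 ± 46.1 against 6.80 ± 0.805 CPM (4.75 ± 0.38, adjusted p = 1.32e-06). BCL2 was higher by 1.70 ± 0.14 (2427 ± 241 against 618 ± 113 CPM, adjusted p = 2.17e-06). SATB1, a chromatin organiser of thymocytes, was at 169 ± 155 against 7486 ± 443 CPM (-5.58 ± 0.37, adjusted p = 2.90e-07), and RAG1 at 29.7 ± 3.63 CPM (-5.51 ± 0.26, adjusted p = 5.00e-08), while DNTT was at 1208 ± 209 CPM (-2.24 ± 0.18, adjusted p = 1.39e-06).

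DNA replication genes were higher for 25 of 27 in cycling early DN-like nuclei (camera adjusted p = 4.91e-11, or 0.0435 with an estimated correlation). This test was not independent either. POLA1 was higher by 3.95 ± 0.18 and UHRF1 by 2.51 ± 0.14. T cell receptor signalling genes were lower for 9 of 18 and higher for 2, or 10 lower adjusted over the list alone (adjusted p = 0.00248, adjusted p = 0.185 with an estimated correlation). TRAT1 had -4.74 ± 0.22, SLA -6.12 ± 0.34, GRAP2 -3.33 ± 0.15 and THEMIS -1.99 ± 0.16. Transcription factors were higher for 6 of 25 and lower for 10, or 7 and 11 adjusted over the list alone (adjusted p = 0.198). CBFB was higher by 2.99 ± 0.22 and TOX by 2.68 ± 0.28, while ETS1 (-1.74 ± 0.14), IKZF3 (-1.97 ± 0.19) and GATA3 (-0.65 ± 0.22) were lower. The call of GATA3 was lost under 8 of 10 alternative settings, among which that of at least 50 nuclei per library left the fit unchanged. Its value was 0.0050, without TMM scaling, when replicate 1 was left out. Notch pathway genes were lower for 5 of 13 and higher for 2 (adjusted p = 0.493), with MAML2 at -5.18 ± 0.28. Cytokine receptor and JAK-STAT genes were higher for 3 of 20 and lower for 9 (adjusted p = 0.198). CISH, a feedback inhibitor of cytokine signals, was at 54.4 ± 8.44 CPM with 0 UMIs in DP-like nuclei, at least 32.7-fold higher, and STAT4 had -2.06 ± 0.19. V(D)J recombination genes were higher for 2 of 10 and lower for 4 (adjusted p = 0.198), with RAG2 at 10.8 ± 15.2 CPM. Stress genes were higher for 5 of 7 and lower for 1, or 2 lower adjusted over the list alone (adjusted p = 0.0690). Apoptosis genes were higher for 3 of 10 and lower for 2 (adjusted p = 0.896), with BMF at -5.48 ± 0.60 and BCL2L1 at -2.29 ± 0.38. Among the largest folds upwards, MICAL2, which oxidises actin, was at 176 ± 12.2 CPM, ASAP2, an ARF GTPase-activating protein, at 208 ± 63.7 CPM and ABLIM1, an actin-binding protein, at 167 ± 7.48 CPM against 0 UMIs. In the other direction BTG2 had 0 UMIs against 219 ± 5.82 CPM, at least 37.8-fold lower, and DTX4, a Notch pathway ubiquitin ligase, 0 UMIs against 71.4 ± 13.5 CPM. HINTW was higher by 0.68 ± 0.12 (adjusted p = 6.74e-04), or by 1.04 when replicate 2 was left out.

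γδ-like nuclei held little recombinase transcript and higher levels of GATA3, TOX and BACH2 than DP-like nuclei. RAG1 was at 28.2 ± 17.9 CPM (-5.65 ± 0.26, adjusted p = 1.04e-07), RAG2 at 10.7 ± 2.35 CPM (-5.39 ± 0.61, adjusted p = 7.43e-05) and DNTT at 193 ± 48.8 CPM (-4.88 ± 0.22, adjusted p = 5.28e-08). BACH2 stood at 3122 ± 156 against 345 ± 6.57 CPM (2.96 ± 0.15, adjusted p = 1.04e-07), GATA3 at 1449 ± 153 against 284 ± 56.8 CPM (2.13 ± 0.19, adjusted p = 6.98e-06) and TOX at 964 ± 58.5 against 72.04 ± 37.7 CPM (3.60 ± 0.27, adjusted p = 1.55e-06). SATB1 fell to 543 ± 254 from 7486 ± 443 CPM (-4.04 ± 0.33, adjusted p = 3.08e-06). IL7R was higher by 4.09 ± 0.65, CCR7 by 4.06 ± 0.54, S1PR1 by 3.64 ± 0.41 and BCL2 by 0.66 ± 0.15. With replicate 1 left out BCL2 had 1.13 and IL7R 99.3 against 0 CPM.

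The test called 1339 genes in γδ-like nuclei, 859 higher and 480 lower. V(D)J recombination genes were lower for 5 of 10 and higher for 1 (camera adjusted p = 0.00389, adjusted p = 0.0929 with an estimated correlation), with LIG4 at 0 UMIs, at least 25.5-fold lower. Antigen presentation genes were higher for 7 of 10, or 8 adjusted over the list alone (adjusted p = 2.88e-04, adjusted p = 0.0929 with an estimated correlation). TAP2 was higher by 2.62 ± 0.36, and BF1 and BF2, whose counts share the doubt about near-identical copies, were at 104 ± 32.1 and 126 ± 23.8 CPM. DNA replication genes were higher for 12 of 27, or 14 adjusted over the list alone (adjusted p = 3.17e-04, adjusted p = 0.0929 with an estimated correlation), with CLSPN, a replication checkpoint mediator, higher by 3.999 ± 0.45 and POLA1 by 1.96 ± 0.20. Interferon response genes were higher for 4 of 9, or 5 adjusted over the list alone (adjusted p = 0.00158, adjusted p = 0.0929 with an estimated correlation), and stress genes for 5 of 7 with 1 lower (adjusted p = 0.00392, adjusted p = 0.318 with an estimated correlation). EPSTI1 was at 45.1 ± 6.82 CPM against 0 UMIs and HSP90AA1 was higher by 3.69 ± 0.25. T cell receptor signalling genes were higher for 6 of 18 and lower for 6, or 7 and 7 adjusted over the list alone (adjusted p = 0.705). TRAT1 (-3.08 ± 0.18) and THEMIS (-2.32 ± 0.16) were lower. Transcription factors were higher for 11 of 25 and lower for 5, or 8 lower adjusted over the list alone (adjusted p = 0.653), with CBFB higher by 3.14 ± 0.22 and FOXP1 at -1.54 ± 0.10. Selection and activation genes were higher for 5 of 12 and lower for 1 (adjusted p = 0.126). The inhibitory receptor gene PDCD1 was higher by 3.62 ± 0.47, ITM2A by 1.78 ± 0.33, and TNFAIP3, an inhibitor of NF-κB, had -2.10 ± 0.36. Other large folds were those of EZR, a linker of membrane and actin (5.83 ± 0.60), FAM129A (5.75 ± 0.44), BTG2 (-5.14 ± 0.65), SH3PXD2A (-3.91 ± 0.23) and MAML2 (-3.79 ± 0.24). With called doublets kept, 73 nuclei had this name and 732 genes were called, 354 higher and 378 lower, and 548 of the 1339 genes were called there in the same direction. CLSPN, POLA1, BCL2 and ITM2A then had 1.46, 0.097, -0.56 and -0.73 and did not pass.

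Cycling γδ-like nuclei held higher levels of TOX, BACH2 and GATA3 than DP-like nuclei. RAG1 and RAG2 had 0 UMIs in them, at least 160.4-fold and 56.8-fold lower than in DP-like nuclei, and DNTT had -5.44 ± 0.24 (adjusted p = 2.35e-08). TOX was higher by 4.47 ± 0.27 (1771 ± 411 against 72.04 ± 37.7 CPM, adjusted p = 1.40e-07), BACH2 by 2.78 ± 0.15 (adjusted p = 6.86e-08) and GATA3 by 2.02 ± 0.19 (adjusted p = 6.17e-06). POLA1 was higher by 3.59 ± 0.18 (adjusted p = 4.54e-08), UHRF1 by 2.29 ± 0.14 and BCL2 by 1.57 ± 0.15. SATB1 had -5.16 ± 0.37 (adjusted p = 5.73e-07) and MAML2 -5.34 ± 0.29 (adjusted p = 6.48e-08).

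Of the 6028 genes 1837 passed in cycling γδ-like nuclei, 1162 higher and 675 lower. DNA replication genes were higher for 20 of 27, or 24 adjusted over the list alone (camera adjusted p = 2.08e-08, adjusted p = 0.0795 with an estimated correlation). V(D)J recombination genes were lower for 5 of 10 and higher for 2 (adjusted p = 0.0313, adjusted p = 0.278 with an estimated correlation), and stress genes higher for 5 of 7 and lower for 1 (adjusted p = 0.0313, adjusted p = 0.393 with an estimated correlation). The antigen presentation list was higher for 5 of 10 (adjusted p = 0.0492, adjusted p = 0.278 with an estimated correlation) and interferon response genes for 5 of 9, or 6 adjusted over the list alone (adjusted p = 0.0472, adjusted p = 0.278 with an estimated correlation). Neither list passed with DESeq2-type size factors. T cell receptor signalling genes were higher for 4 of 18 and lower for 8, or 9 lower adjusted over the list alone (adjusted p = 0.141), with TRAT1 at -4.12 ± 0.21 and SLA at -4.65 ± 0.30. Transcription factors were higher for 11 of 25 and lower for 7, or 8 lower adjusted over the list alone (adjusted p = 1.000), with CBFB higher by 3.38 ± 0.22. IKZF2 was higher by 1.04 ± 0.21, CCR7 by 3.71 ± 0.57, S1PR1 by 3.68 ± 0.42 and HSP90AA1 by 4.92 ± 0.24. The mitotic factor FOXM1 was at 235 ± 40.5 CPM against 1 UMI, and PLK1 at 60.01 ± 10.3 CPM against 0 UMIs. ABCA1 (-3.92 ± 0.34), BMF (-4.54 ± 0.56) and BCL2L1 (-3.31 ± 0.44) were lower, with BMF lower still without replicate 2. With called doublets kept, 944 nuclei had this name, and UHRF1 was at 0.43 and did not pass. Whether γδ-like and cycling γδ-like nuclei differ from each other was not tested.

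The list medians, means and camera directions differed in sign for 25 of the 180 list results, none of which passed. These were selection, Notch, stress and circadian genes in the T lineage, stress genes in B-like nuclei, V(D)J and apoptosis genes in dendritic-like nuclei, and T cell receptor signalling, selection and stress genes in macrophage-like nuclei. Among the stages they were trafficking, apoptosis and ribosomal protein genes in CD4 SP-like nuclei, apoptosis, matrix and interferon genes in cycling DP-like nuclei, and Notch genes in cycling early DN-like nuclei. In γδ-like nuclei they were T cell receptor signalling, Notch, clearance and mitochondrial genes, and in cycling γδ-like nuclei cytokine receptor, transcription factor, Notch and apoptosis genes.

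The 2 libraries of the group were compared without a test, since no condition differs between them. Across 4347 genes with at least 50 CPM in one library, the log2(CPM + 1) values correlated across genes with a Pearson's r of 0.946, where genes are not independent replicates, and 96 genes differed by more than 2-fold. The chi-square between them was 8.98 per degree of freedom over genes with at least 10 UMIs. They shared only 10 barcode sequences, which excluded repeated deposition of one library. Of the 96 genes, 89 were higher in replicate 2 and 7 in replicate 1. RASSF1, a tumour suppressor gene, was at 5.73 CPM in replicate 1 and 67.3 CPM in replicate 2, and among genes with a symbol the largest ratios towards replicate 2 also included MTO1, C12orf57, CSK and ACBD4. Towards replicate 1 they included BNIP3L, M6PR, C9orf85, NR2C2 and EIF4B. The gene with most UMIs, ENSGALG00010000588, which carries no symbol, took 4.97% and 4.31% of UMIs.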

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

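Apart from the test of UMIs removed nucleus by nucleus, the tests in this part were chosen only after the results were seen. One signal lay in nuclei that no comparison used. The 644 nuclei removed as doublets held 945 UMIs of CHGA, which encodes chromogranin A, a protein of the hormone granules of neuroendocrine cells. These were 352 UMIs in 4 nuclei of replicate 1 (489.9 CPM of the removed nuclei) and 593 UMIs in 7 nuclei of replicate 2 (533 CPM), above the 4.18 and 2.70 CPM that a count of 0 allows, while the analysed nuclei held 4.95 and 11.96 CPM. In a clustering with called doublets kept, the CHGA-led cluster had 28 called nuclei with 1.78 times the T-lineage marker share of its 31 uncalled ones (no like baseline, with 24 UMIs of CHGA against 940), at 12.6% of the level of T-lineage nuclei, which left open whether they were doublets.

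The 2 libraries differed by more than 2-fold in 96 genes, of which 89 were higher in replicate 2, with a median log2 ratio of 1.58 over all nuclei. Different shares of classes and stages are argued against, since the median was 2.16 within DP-like nuclei alone and between 1.74 and 1.91 in 4 other stages. UMIs removed nucleus by nucleus in replicate 1, as a correction for free RNA may do, remain a candidate explanation: of the nuclei of replicate 1 with a UMI of such a gene, 30.3% held 2 or more of it, against 11.6% (95% range 11.1% to 12.03% over 200 draws) when replicate 2 was thinned to the same totals, and control genes gave 13.1% against 12.9% (12.3% to 13.4%). More cytoplasmic RNA in replicate 2 cannot be told apart, because the median log2 ratio was -0.77 over 52 ribosomal protein genes and 1.15 over a first set of 2 genes, which was widened after its value was seen. No biological explanation was tested, since the design names no difference between the libraries.

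Epithelial-like nuclei held the muscle genes TTN, at 1919 ± 782 CPM against 5.38 ± 2.51 in T-lineage nuclei (938 UMIs in 87 of 165 nuclei), and LDB3, at 364 ± 77.0 against 1.57 ± 1.02 CPM. Free RNA stays open: a correction may have lowered TTN in T-lineage nuclei, at 0.292% of the epithelial-like level. Nuclei with TTN had 1.92 times the T-lineage marker share of those without it at 1000 UMIs each (counting interval 1.02 to 3.81, from 33 and 15 UMIs), past the bound set for doublets, but that share was 1.77% of the level of T-lineage nuclei, which argues against doublets with them by a criterion added after the ratio was seen. RNA or nuclei of muscle cannot be told apart, because the median ratio to the T-lineage level was 2.38 over the 8 other muscle genes and 0.451 over the first 4 tried (NEB, MYBPC1, ACTN2 and TNNT3), with MYBPC1 and TNNT3 at 0 UMIs but TRDN, MYPN and TNNI2 at 61.4, 34.5 and 30.7 times it from 4, 9 and 2 UMIs, while T-lineage nuclei also held 374 UMIs of NEB and 211 of TNNT3. No biological explanation was tested.

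The 5 heat-shock genes HSPA8, HSP90AA1, HSPH1, HSPD1 and DNAJA1 summed to 44.0 ± 4.40 CPM in DP-like nuclei, 785 ± 237 in CD4 SP-like nuclei and between 958 and 1792 CPM in the 4 other named stages. UMIs removed from shallow nuclei are argued against, since 340 nuclei of the other stages no deeper than the median DP-like nucleus held 28.6 times the level of DP-like nuclei of that depth (17.7 to 49.0, from 137 and 19 UMIs). This was the third form of that test, after a comparison of shallow with deep nuclei (ratios of 0.794 in CD4 SP-like and 0.733 in γδ-like nuclei) and one on 13 shallow CD4 SP-like nuclei with 2 UMIs, which left it open. The cell cycle is argued against as the whole difference by the 17.8-fold ratio of CD4 SP-like to DP-like nuclei, neither of which was named cycling. A correction for free RNA that differed between clusters was not tested and stays open, and no biological explanation was tested.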

How the results depend on the processing

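Apart from the numbered clusters in the stage fit, chosen after seeing the data, the alternatives were planned. Of single-gene alternative values, 2379 kept direction and side of the threshold or, with 1 library left out (no test), lay within 1 library SD. These include stage values with at least 50 nuclei (fit unchanged). Another 327 lay over 1 SD away, but an SD of 2 libraries cannot judge stability. Of others, 57 kept only direction and 17 changed sign. No cause was tested below except where given.

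With at least 400 genes per nucleus, B-like nuclei made up 1.52% (1.11% with the settings of the report), dendritic-like 0.799% (0.705%), epithelial-like 2.18% (1.63%), macrophage-like 0.945% (0.721%) and T-lineage nuclei 92.4% (94.9%), and within the T lineage CD4 SP-like nuclei 9.02% (5.24%), cycling DP-like 22.4% (16.1%), cycling early DN-like 5.29% (3.52%), cycling γδ-like 6.21% (3.41%) and γδ-like 6.33% (6.69%). With called doublets kept, T-lineage nuclei were at 94.4%, epithelial-like at 1.78%, cycling γδ-like at 9.33% and γδ-like at 0.717%. At resolution 0.5, CD4 SP-like nuclei were at 9.68% and γδ-like at 10.03%, and at resolution 2 the T lineage was at 94.2% and CD4 SP-like at 7.48%. CD4 SP-like nuclei were at 4.13% with no scaling by library. With held-out genes as features they were at 3.32%, cycling DP-like at 11.6% and γδ-like at 7.49%, and with clustering on 70% of UMIs at 4.18%, 12.5% and 9.96%. With 1 library left out, the T lineage ranged from 94.7% to 95.7%, macrophage-like from 0.617% to 0.764%, DP-like from 27.8% to 41.9% (31.0%), CD4 SP-like from 3.89% to 4.84%, cycling γδ-like from 1.81% to 4.08% and γδ-like from 7.27% to 17.2%. Dendritic-like nuclei were at 0.967% without replicate 2, and cycling DP-like at 6.17% and cycling early DN-like at 3.91% without replicate 1. The other values of these shares moved by less than 1 SD.

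DESeq2 called 460 genes in B-like (289) and 350 in dendritic-like nuclei (223). With no filter on low counts 2671 were called in epithelial-like nuclei (1495) and 1399 in the T lineage (756), where more genes enter the test. With at least 50 nuclei per library epithelial-like nuclei had 2550, in a fit of 3 classes and 5669 genes. Doublets kept gave 469 in the T lineage, with erythroid-like in place of dendritic-like nuclei in the fit, and 732 in γδ-like nuclei (1339), a name that 73 nuclei then had. Testing on 30% of UMIs gave 111 in dendritic-like, 602 in epithelial-like, 198 in macrophage-like (382) and 455 in T-lineage nuclei, from fewer UMIs, and resolution 2 gave 391 in the T lineage in a fit of 7 classes. The DESeq2 test, but not its size factors alone, moved the split of higher against lower calls by over 10 points, to 543 and 551 in the T lineage (498 and 258), 855 and 262 in cycling DP-like (1032 and 584), 1100 and 516 in cycling early DN-like (1187 and 870) and 754 and 253 in γδ-like nuclei (859 and 480). In the T lineage no filter moved it to 1192 and 207 and doublets kept to 372 and 97, in γδ-like nuclei doublets kept to 354 and 378, and in B-like nuclei (212 and 77) no filter to 253 and 43, at least 50 nuclei to 276 and 37, doublets kept to 254 and 41 and resolution 2 to 237 and 33. Lower calls outnumbered higher ones in epithelial-like nuclei (780 and 715) with DESeq2 (806 and 836), at least 50 nuclei (1121 and 1429) and doublets kept (758 and 900).

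With an estimated correlation, camera passed 0 lists in B-like (5), dendritic-like (3), epithelial-like (3), macrophage-like (1), T-lineage (8), CD4 SP-like (4), cycling γδ-like (5) and γδ-like nuclei (5), 1 in cycling DP-like (3) and 1 in cycling early DN-like nuclei (2). At an unadjusted p under 0.05 with that correlation, 3, 2, 2, 1, 5, 3, 3 and 4 lists passed in the 8 contrasts at 0. DESeq2-type size factors left 3 lists in cycling γδ-like nuclei (5).

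BCL2 was at -0.17 in B-like nuclei (0.43) with at least 50 nuclei. In CD4 SP-like nuclei (0.00) it was at -0.061 with no filter, -0.69 with doublets kept (adjusted p = 0.00638), -0.16 on 30% of UMIs, -0.070 at resolution 2 and -0.065 with numbered clusters added, and HINTW (-0.08) was at 0.041 with doublets kept, 0.062 on 30% of UMIs and 0.27 at resolution 2. PRKDC in the T lineage (0.03) was at -0.029 with DESeq2-type size factors, -0.032 with DESeq2 and -0.025 at resolution 2. None of these passed in the report. IKZF2 in CD4 SP-like nuclei (-1.86) was at 1.23 at resolution 0.5. BCL2 and ITM2A in γδ-like nuclei (0.66 and 1.78) were at -0.56 and -0.73 with doublets kept. GATA3 in cycling early DN-like nuclei (-0.65) was at 0.0050 without replicate 1 and -0.82 without replicate 2, and DNTT in dendritic-like nuclei (6.77) at -2.74 without replicate 2, which held all its UMIs there, and at 5.71 without replicate 1. Of 542 called single-gene values with 1 library left out, 33 lay over 1.5 times from the value of both libraries, among the classes those of ABCA1, HSP90AA1 and SH3PXD2A in B-like, HSPA8 in T-lineage, ABCG1, ID2, NFATC1, NUAK1 and DNTT in dendritic-like, HMGB1, IL6ST and RUNX3 in epithelial-like, and BCL2, SRSF3 and TGFBR2 in macrophage-like nuclei.

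The library was a block in the tests, as the classes and stages of 1 library share it. Deviations of the same library correlated with a median of 0.0994 (0.0147 to 0.223, 10 pairs) between classes and 0.236 (0.0950 to 0.459, 15 pairs) between stages. With no replicate block the calls were 322 in B-like, 251 in dendritic-like, 1538 in epithelial-like, 394 in macrophage-like, 835 in T-lineage, 1179 in CD4 SP-like (1420), 1345 in cycling DP-like (1616), 1845 in cycling early DN-like (2057), 1601 in cycling γδ-like (1837) and 1099 in γδ-like nuclei, all within 1.5 times.

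No dendritic-like class was found with doublets kept, at resolution 0.5, with at least 50 nuclei or without replicate 1, no macrophage-like class with at least 50 nuclei, no cycling DP-like stage with doublets kept, at resolution 0.5 or 2 or without replicate 2, no cycling early DN-like stage without replicate 2, and no cycling γδ-like stage at resolution 0.5 or on 70% of UMIs.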

Other observations

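The tests in this part, on T-lineage clusters without a name, were chosen only after the clusters were seen. They add 4 such clusters to the stage fit, over 6541 genes with 9 residual degrees of freedom, and compare each with DP-like nuclei by edgeR's quasi-likelihood test. Lists that passed camera with an estimated correlation are named.

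Cluster 5, led by GNLY and PRKCH, made up 8.15% ± 0.831 of T-lineage nuclei. KLF2, ID2, IL2RB and IL18R1 had 0 UMIs in DP-like nuclei and stood at 152 ± 0.815, 136 ± 71.3, 107 ± 15.5 and 110.3 ± 9.78 CPM. IL7R was higher by a log2 fold change of 5.96 ± 0.55 (adjusted p = 1.03e-07), S1PR1 by 5.03 ± 0.41 (adjusted p = 2.36e-08) and FOXO1 by 4.95 ± 0.41 (adjusted p = 2.67e-08). DNTT had -6.96 ± 0.23, and RAG2 had 0 UMIs. Genes of V(D)J recombination were lower for 5 of 10 and higher for 1 (adjusted p = 4.46e-04, or 0.0405 with an estimated correlation). Of 1882 genes that passed, 1138 were higher. Antigen presentation genes were higher for 10 of 11 and lower for 1 (adjusted p = 2.15e-06, or 0.00675 with an estimated correlation).
Cluster 12, 1.41% ± 0.453 of T-lineage nuclei, had TNFRSF18 and TNFRSF4 among its leading genes, and also NR4A3 and EGR3, which were no clustering features. NR4A3, an early response gene of receptor signals, stood at 3463 ± 1329 against 14.5 ± 0.351 CPM (adjusted p = 7.42e-10), IKZF2 was higher by 1.90 ± 0.20 (adjusted p = 1.14e-06) and BACH2 by 3.82 ± 0.16 (adjusted p = 4.62e-12), and DNTT and RAG2 had 0 UMIs. Of 1489 genes that passed, 800 were higher. Selection and activation genes were higher for 7 of 12 and lower for 1, or 9 higher adjusted over the list alone (adjusted p = 8.27e-05, or 0.0448 with an estimated correlation), and antigen presentation genes for 9 of 11 and 1 (adjusted p = 6.67e-05, or 0.0172 with an estimated correlation). Stress genes, which handling can induce, were higher for 7 of 10 and lower for 1 (adjusted p = 0.00108, or 0.165 with an estimated correlation). Clusters 5, 2 and 4 had 7, 6 and 4 higher over the same low DP-like level.

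Cluster 2, 14.4% ± 0.361 of T-lineage nuclei, was led by SHANK2 and SOX4 and held TOX at 1691 ± 45.6 against 72.04 ± 37.7 CPM (adjusted p = 2.07e-09), EGR3 at 415 ± 184 against 19.6 ± 7.64 CPM (adjusted p = 5.31e-06) and RAG1 at 50.7 ± 43.2 against 1143 ± 121 CPM (adjusted p = 2.01e-08). In it 1336 genes passed, 744 of them higher. Antigen presentation genes were higher for 6 of 11 and lower for 1, or 7 higher adjusted over the list alone (adjusted p = 3.65e-04, or 0.0311 with an estimated correlation).
Cluster 4, 9.79% ± 0.238, was led by CLGN and CDK6. DNTT (0.68 ± 0.15, adjusted p = 0.00407) and BCL2 (1.13 ± 0.15, adjusted p = 2.02e-05) were higher there than in DP-like nuclei, RAG1 was lower (-1.54 ± 0.28, adjusted p = 6.08e-04), and 12 of 27 DNA replication genes were higher, or 17 adjusted over the list alone (adjusted p = 1.65e-06, adjusted p = 0.0155 with an estimated correlation). Receptor signalling genes of T cells were lower for 9 of 18 and higher for 1 (adjusted p = 1.70e-05, or 0.0418 with an estimated correlation). Of 1164 genes that passed, 695 were higher. Whether these clusters are stages, and how they differ from each other, was not tested.

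A cluster of 40 nuclei, 0.392% ± 0.147 of all nuclei, stayed unnamed. APOA1, KCNIP4 and APOB were among its leading genes, and it carried markers of both thrombocytes and epithelium.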
